A study of Caenorhabditis elegans with 9 samples.

How the data were processed

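Poly(UG)-tailed (pUG) RNAs of oma-1 were sequenced from adult Caenorhabditis elegans on an Illumina MiSeq, per the series text. RNA was extracted with TRIzol and the libraries came from a custom preparation, per the labels' protocols. There were 9 libraries, 1 for each of 9 conditions, and no condition had a replicate. Wild-type animals of strain N2 were fed bacteria with the empty vector L4440, with the oma-1 clone of the Ahringer RNAi library, or with the clone pAS74, which the series text places on exon 6 of oma-1. Strain YY1449, which carries rde-3(ne3370), was fed L4440 or the Ahringer clone. The remaining 4 libraries came from the F1, F2, F3 and F4 descendants of pAS74-fed animals.

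For each library the authors deposited 2 tables. The first table gave, per the file headers, a chromosome IV coordinate for every tail site and the number of reads there, which is a raw count with no normalization. The second table listed the reads, with adapters trimmed from Read 2, split into an oma-1 portion and a pUG portion. The submitters' processing notes name UMI-tools, cutadapt, STAR, SAMtools and bedtools without versions. Their roles and order, the genome build and whether coordinates start at 0 or 1 are not given in the sources used here. Whether reads with the same molecular identifier were collapsed is not given either. The tables hold the oma-1 pUG reads of a library and not its whole depth, so counts were compared as listed, and a difference in sequencing depth between libraries would change them in proportion. The counts of the site tables were the main source. The sequences of 24 reads in 5 libraries are not used here, while the counts of the site tables include those reads.

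No genome sequence was used. The gene was identified by name only, from the RefSeq gene table of assembly WBcel235, where oma-1 is on chromosome IV. The spliced sequence of the sequenced part of oma-1 was rebuilt from the oma-1 portions by extending 19-mers held by at least 3 reads. It was 953 nt long and had an open frame with 0 stop codons, and its position 1 fell on coordinate 8889152. Each read was then placed by its last 25 oma-1 bases with at most 5 mismatches. Steps between read ends and the authors' coordinates located 4 introns of 46, 42, 44 and 43 nt, which cut the sequence into 5 exon segments that begin at positions 1, 188, 420, 568 and 824. The second intron (chromosome IV, 8889617 to 8889658) and the third (8889807 to 8889850) were bounded exactly by unspliced reads. The first and the fourth were bounded only to within the gap between the nearest sites. Between 99.8% and 100% of the listed reads of each library fell on the authors' own site. Exon numbers of the annotated gene could not be assigned without a genome, so the planned share of reads in exon 6 was replaced by shares per exon segment and relative to the 2 CCCH zinc fingers, which were found as the protein motif C-X8-C-X5-C-X3-H in the open frame. All positions below count nt along the rebuilt spliced sequence, and coordinates are those of the authors' tables.

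Counts were given exact Poisson 95% intervals, and shares exact Clopper-Pearson 95% intervals. A count of 0 was taken to allow up to 3 reads. These intervals and limits cover counting error only, since PCR reads are not independent molecules. Medians and their differences were given 95% intervals from 2000 bootstrap resamples of sites. Sites were compared at equal depth by drawing 874 reads without replacement 1000 times. Libraries with fewer than 10 reads or 10 sites were left out of medians, overlaps and junction bases. Shared sites were set against the product of the 2 site numbers divided by the 928 positions of the span that holds sites. This takes every position as equally likely and neighbouring positions as independent. With 1 library per condition, no test between conditions was made. The 1 p-value given, an exact binomial test in the closing section, compares the site positions of 2 libraries with random positions. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots matplotlib 3.10.9.

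The functions were tested on simulated data. In 6000 simulated reads with 0.5% errors the rebuilt 931 nt were 100% equal to the simulated sequence, 100% of reads were placed at their simulated end, and 21 of 24 unspliced reads were found. Resampling the sites of each library in 300 simulations gave the 95% intervals of the read-weighted median a coverage of 79.3% to 95.3%, so these intervals are too narrow where a few sites hold most reads. With each site counted once, coverage was 93.3% to 97.3%. The simulations drew sites independently, so they cannot show the effect of neighbouring sites that depend on each other. Clopper-Pearson intervals of site shares take sites as independent too.

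The sites named in the text followed a rule set before the data were examined. It took the 5 sites with most reads in each library with at least 10 sites, every site in a smaller library, and up to 5 sites present in fed animals and all 4 descendant generations with the highest summed share of reads. Alternatives set at the same time were identical reads counted once, rows of the read list, perfect UG tails of at least 18 nt, at least 2 or 5 reads per site, merging of sites within 3 nt, each site counted once, removal of the most-read site, means, and equal depth. The regions, the comparisons of F1 with F3 and F4, removal of the 5 most-read sites, merged sites at equal depth, for differences in position, counted once or for junction bases, means and identical reads for differences in position, and the random-start background for junction bases were added after seeing the data. The planned background of the whole transcript was not run, because only the sequenced part was rebuilt.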

Results

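RNAs of oma-1 that carried a 3' tail of alternating U and G were sequenced to ask where such tails begin, whether they need rde-3, and how the tailed RNAs change in the descendants of treated animals. The gene oma-1 encodes a CCCH zinc-finger protein of oocyte maturation, and rde-3 encodes a nucleotidyltransferase that adds pUG tails. A tail site is the last oma-1 base before the tail. The 9 libraries listed between 0 and 11023 oma-1 pUG reads. Wild-type animals had 0 reads on empty vector, 874 (95% Poisson interval 817 to 934) on the Ahringer clone and 2531 (2433 to 2632) on pAS74. The descendants of pAS74-fed animals had 11023 (10818 to 11231) reads in F1, 9209 (9022 to 9399) in F2, 6754 (6594 to 6917) in F3 and 907 (849 to 968) in F4. The rde-3 mutant had 7 (2.81 to 14.4) reads on empty vector and 0 on the Ahringer clone. No condition was replicated, so all differences below are between single libraries, and total sequencing depth was not used to scale them.

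The first comparison asked whether feeding of oma-1 dsRNA gave tailed oma-1 RNA and whether rde-3 was needed. On the Ahringer clone, wild-type animals had 874 reads at 54 sites and the mutant had 0 reads, which allows up to 3. With the floor of 3 reads taken for the mutant, the listed reads were 291-fold higher in the wild type. The exact conditional binomial 95% interval of the ratio began lower, at 236. Both values were the same with wild-type animals on empty vector, also at 0 reads, as the reference. Counted as sites, the wild type on the Ahringer clone was 18-fold above a floor of 3. On empty vector the order was the opposite, with 7 reads in the mutant and 0 in the wild type, a ratio of wild type over mutant between 0 and 0.694 by the same interval. The 7 mutant reads lay at 7 sites of 1 read each, at chromosome IV coordinates 8889259, 8889413, 8889446, 8889496, 8889510, 8889551 and 8889762, in exon segments 1 to 3.

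The second comparison set the 2 dsRNA clones side by side in wild-type animals. By reads, most tails in both libraries lay in the first 3 exon segments, which reach up to position 567 of 953. By sites this was less marked. Segment 4 held 15.5% of pAS74 sites and 20.4% of Ahringer sites, and segment 5 held 5.95% and 0%. The read shares were as follows. Segment 1 held 51.1% (site bootstrap interval 7.0 to 75.7) of pAS74 reads and 31.2% (0.536 to 64.1) of Ahringer reads, segment 2 held 30.4% (12.1 to 63.7) and 35.7% (6.97 to 67.6), and segment 3 held 15.6% (5.39 to 37.9) and 28.1% (10.8 to 62.2). Segment 4 held 2.21% and 4.92%, and segment 5 held 0.632% of pAS74 reads and 0 of 874 Ahringer reads. The read-weighted median position was 144 nt (108 to 394) on pAS74 and 340 nt (108 to 428) on the Ahringer clone, a difference of 196 nt (-249 to 318), which lay within the site-to-site error. With each site counted once the medians were 426 nt and 421 nt, a difference of -5 nt (-86 to 45). Of the 54 Ahringer sites, 27 were also pAS74 sites, against 4.89 expected by chance, a ratio of 5.52.

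The most-read site on pAS74 was at coordinate 8889259 (position 108, segment 1), where the oma-1 sequence ended in ACUUGUCUCAAACUAAUCCG. It held 809 reads, 32.0% (Clopper-Pearson interval 30.1 to 33.8) of the library. Next were 8889256 with 8.61%, 8889554 in the first zinc finger with 6.72%, 8889194 with 6.60% and 8889567, also in the first finger, with 5.14%. On the Ahringer clone the site at 8889537, where the sequence CAAGACUGUGAUCUGCCAAG reaches into the first finger, led with 215 reads or 24.6% (21.8 to 27.6). The site at 8889259 followed with 22.2% (19.5 to 25.1), then 8889227 with 7.89%, and 8889663 and 8889667 between the fingers with 5.84% and 5.61%.

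**Figure D1:**
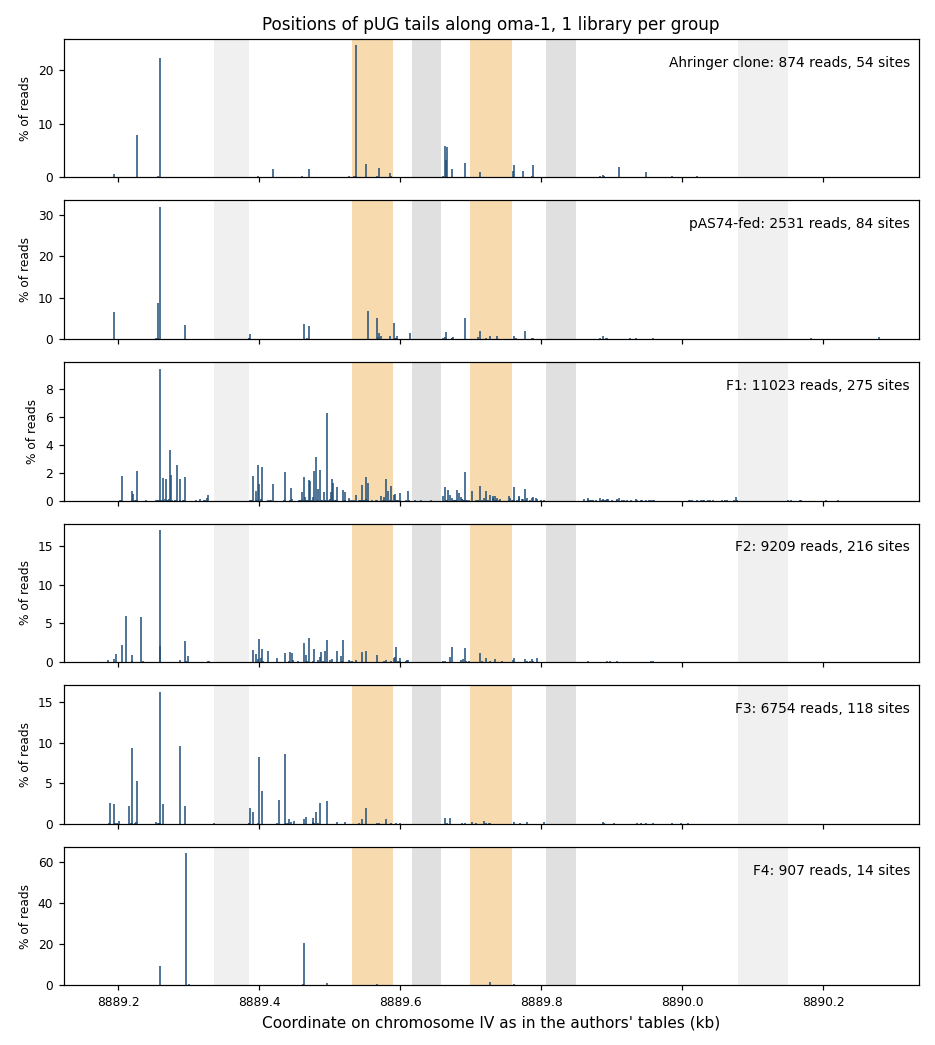
Share of listed reads at each tail site (vertical lines, percent of the library's reads) along chromosome IV in 6 libraries, with the zinc fingers in orange, introns 2 and 3 in grey and the gaps within which introns 1 and 4 lie in pale grey; y axes differ in scale. The site at 8889259 holds 9.43% to 32.0% of reads in every panel, and reads 3' of the second finger make up 12.5% on the Ahringer clone and 0.662% in F4.

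The third comparison followed tailed RNAs through the 4 generations after pAS74 feeding. Listed reads fell by generation from 11023 in F1 to 907 in F4, and F1, F2 and F3 each listed more than the 2531 of the fed animals. At an equal depth of 874 reads, fed animals had 58.0 sites (95% of draws 52.0 to 64.0), F1 had 126 (115 to 137), F2 had 110 (101 to 119), F3 had 60.9 (54 to 69) and F4 had 13.9 (13 to 14). With sites within 3 nt merged, the order was 37.0, 74.96, 63.3, 45.8 and 8.96. The 5 most-read sites held 59.0% of reads in fed animals, 24.9% in F1, 35.1% in F2, 51.9% in F3 and 96.7% in F4.

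Tails in later generations lay more often 5' of the zinc fingers. The share of reads 5' of the first finger was 59.7% (site bootstrap interval 22.7 to 81.5) in fed animals, 71.0% (58.6 to 80.6) in F1, 78.2% (65.1 to 87.6) in F2, 92.3% (83.8 to 96.6) in F3 and 97.0% (62.0 to 99.7) in F4. The share of sites there was 25% (Clopper-Pearson interval 16.2 to 35.6) in fed animals, 41.2% (35.3 to 47.3) in F1, 50% (43.1 to 56.9) in F2, 56.4% (46.9 to 65.6) in F3 and 64.3% (35.1 to 87.2) in F4. With neighbouring sites merged these became 24.4%, 33.3%, 37.4%, 42.2% and 55.6%. Segment 3 held 15.6% of reads in fed animals, 15.3% in F1, 10.9% in F2, 3.38% in F3 and 2.09% in F4.

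The read-weighted median position was 144 nt in fed animals, 281 nt (201 to 299) in F1, 216 nt (108 to 296) in F2, 137 nt (108 to 240) in F3 and 145 nt (108 to 299) in F4. None of the steps between consecutive generations exceeded its error. The differences were 137 nt (-159 to 191) from fed animals to F1, -65 nt (-181 to 65.0) from F1 to F2, -79 nt (-169 to 95) from F2 to F3 and 8 nt (-95 to 162) from F3 to F4. From fed animals to F4 the difference was 1 nt (-254 to 158). With each site counted once the medians were 426, 385, 332, 288 and 265 nt in that order, and the difference from fed animals to F4 was -161 nt (-303 to -46.6). From F1 to F3, a pair added after the data were seen, it was -97 nt (-141 to -25). When sites within 3 nt were also merged the medians were 453, 435, 418, 383 and 299 nt, and the interval of each of these differences included 0.

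**Figure D2:**
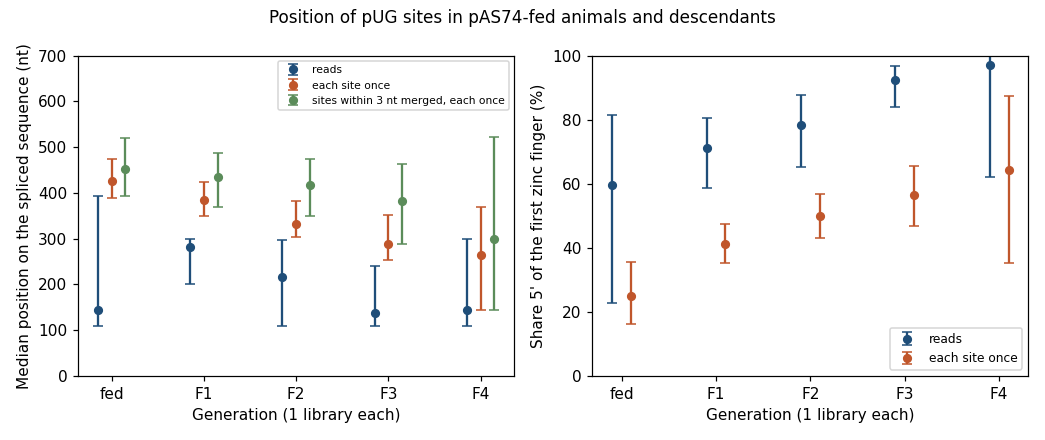
Left, median tail position on the spliced sequence (nt, with 95% site bootstrap intervals) by reads, by sites and by merged sites in fed animals and F1 to F4; right, share of reads (bootstrap intervals) and of sites (Clopper-Pearson intervals) 5' of the first zinc finger (percent). The share of sites goes from 25% in fed animals to 64.3% in F4, while the read-weighted median is 144 nt in fed animals and 145 nt in F4.

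Among descendants the site at 8889259 led in F1 with 9.43% (8.89 to 9.99), in F2 with 17.05% (16.3 to 17.8) and in F3 with 16.3% (15.4 to 17.2) of reads, and held 9.59% (7.75 to 11.7) in F4. In F1 it was followed by 8889496 with 6.23%, 8889273 with 3.61%, 8889481 with 3.11% and 8889283 with 2.56%. In F2 it was followed by 8889211 with 5.99%, 8889233 with 5.89%, 8889471 with 3.11% and 8889400 with 3.04%. In F3 the next sites were 8889288 with 9.52%, 8889220 with 9.37%, 8889437 with 8.56% and 8889400 with 8.20%. All of these lay 5' of the first finger, in segments 1 and 2. In F4 a single site at 8889296, after UUUGGUUACUCAAACUGCUA, held 580 reads or 63.9% (60.7 to 67.1), and 8889463 held 20.6% (18.03 to 23.4). The remaining F4 sites among its first 5 were 8889727 in the second finger with 1.54% and 8889496 with 0.992%.

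Sites present in fed animals and in all 4 descendant generations numbered 7. Beside 8889259, the ones with the highest summed share were 8889463, 8889295, 8889567 and 8889727. The site at 8889463 held 3.52% of reads in fed animals, 1.71% in F1, 2.51% in F2, 0.592% in F3 and 20.6% in F4. The site at 8889295 held 3.40%, 1.70%, 2.76%, 2.21% and 0.331% in that order. The site at 8889567, in the first finger, held 5.14%, 0.0635%, 0.858%, 0.104% and 0.662%. Sites of fed animals recurred in F1 at 2.36 times the number expected by chance (58 shared), in F2 at 2.35 times (46), in F3 at 2.83 times (30) and in F4 at 5.52 times (7). Sites of the Ahringer library, which was not the parent of these animals, did so at 2.53 (40), 2.78 (35), 3.38 (23) and 4.91 (4) times. These were higher than for fed animals in F1, F2 and F3 and lower in F4. Recurrence above the chance number was thus not particular to the sites of the parents. Consecutive generations shared 135 sites between F1 and F2, 72 between F2 and F3 and 9 between F3 and F4. These were 2.13, 2.64 and 5.10 times the chance number. The highest possible ratio is larger where libraries hold fewer sites, so the rise does not show growing reuse of sites. As a share of the smaller library's sites, consecutive generations shared 62.5%, 61.5% and 64.3%. Fed animals shared 69.0% with F1, 54.8% with F2, 35.7% with F3 and 50% with F4 on that measure. The first 3 of these are shares of the 84 fed sites, and the 50% is 7 of the 14 F4 sites, so it shows no return of fed sites in F4.

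The base before the tail was most often G. G was the last oma-1 base at 47.0% (Clopper-Pearson interval 35.9 to 58.3) of sites in pAS74-fed animals, 48.1% (34.3 to 62.2) on the Ahringer clone, 35.7% (29.97 to 41.7) in F1, 38.9% (32.3 to 45.7) in F2, 36.8% (28.0 to 46.2) in F3 and 42.9% (17.7 to 71.1) in F4. G made up 21.6% of the span, but a templated G or U that continues the repeat is counted as oma-1 sequence by the authors' placement, and tails started at random positions gave G at 30.4% under that rule. The intervals of the fed, Ahringer and F2 libraries lay above 30.4%, and those of F1, F3 and F4 included it. The junction was ambiguous in 64.6% (F3) to 89.8% (fed) of reads outside F4, and in 13.2% of F4 reads. Whether G was the last oma-1 base is therefore unsettled for most reads outside F4. With neighbouring sites merged into the most-read one, G preceded 62.2% of fed, 71.0% of Ahringer, 55.6% of F1, 59.6% of F2, 56.3% of F3 and 66.7% of F4 sites, for which no merged background was computed. By reads, G preceded the tail in 76.8% of fed, 83.1% of Ahringer, 65.1% of F1, 64.2% of F2 and 51.3% of F3 reads, but in 13.8% of F4 reads, where A at the site 8889296 made up most of the 84.7% with A. C preceded 14.3% to 22.2% of sites per library, around the 20.6% of random starts, and 0.711% to 8.47% of reads. Mismatches in the last 3 oma-1 bases occurred in 0.115% to 0.792% of reads per library, below the 1.26% to 1.88% at bases 14 to 16 from the end. In 0% of reads did the next templated base equal the first tail base, so the authors' split ends at the longest templated match, which keeps mismatches at the end low. Whether untemplated bases lie between oma-1 and the tail was therefore left open.

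The listed part of the tail had a median of 9 nt (quartiles 3 to 16) in pAS74-fed animals, 13 nt (5 to 21.5) on the Ahringer clone, 10 nt (5 to 21) in F1, 10 nt (3 to 18) in F2, 7 nt (3 to 13) in F3 and 12 nt (10 to 14) in F4. The longest was 67 nt, in F2. These are lengths as listed, since how the repeat was primed and trimmed is not given in the sources used here. A tail was called perfect where U and G alternated throughout, whatever its length, so a single U counted as perfect. Short tails thus have little room to be irregular, and tails of up to 3 nt made up 11.4% (F4) to 35.4% (fed) of reads. By this rule the tail was a perfect UG repeat in most reads of each library except F4. It was irregular in 6.999% (6.03 to 8.06) of reads in pAS74-fed animals, 24.6% (21.7 to 27.6) on the Ahringer clone, 17.3% (16.6 to 17.99) in F1, 15.7% (14.9 to 16.4) in F2, 11.01% (10.3 to 11.8) in F3 and 66.9% (63.8 to 70.0) in F4. In F4, 568 of the 580 reads at 8889296 began their tail with UGUU. At the site 8889259 the whole listed tail was a single U in 406 of 809 reads in fed animals and in 86 of 87 in F4.

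**Figure D3:**
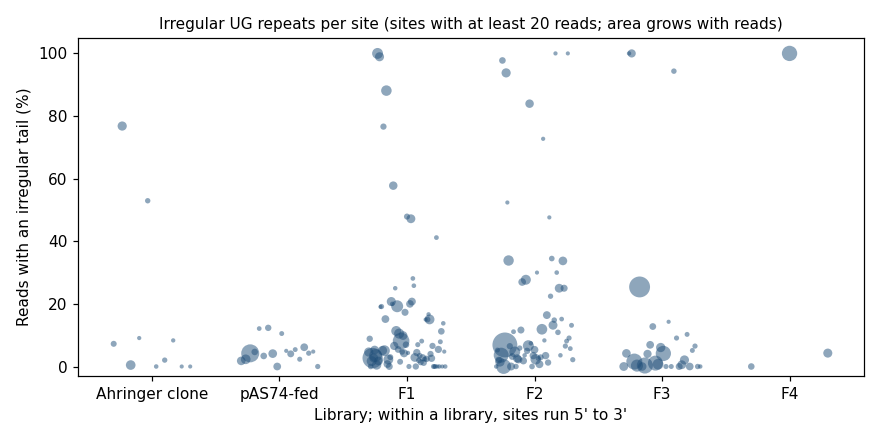
Share of reads with an irregular tail (percent, y axis) at each site with at least 20 reads, in 6 libraries. Tails of any length count, so a single U is not irregular. Within a library points run 5' to 3' and their area grows with the number of reads. No site of the pAS74-fed library reaches 80%, nor does any on the Ahringer clone, where the highest is 76.8%, while 3 sites of F1, 5 of F2, 3 of F3 and 1 of F4, at 100% of 580 reads, do.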

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

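The tests on the mutant's reads in this part were chosen after the result was seen. The reads that keep an intron were also singled out after the data were seen.

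The listed reads on the Ahringer clone minus those on empty vector had opposite signs in the 2 strains, at 874 in the wild type and -7 in the rde-3 mutant. There was 1 library of each kind, counts were not scaled for depth, and the difference was not tested. Addition of tails at random positions without the mutated gene is argued against by position. The test takes every position of the span as equally likely, so it does not bear on tails added without rde-3 at preferred sites. All 7 mutant sites fell on the 63 F2 sites with at least 20 reads, which make up 6.79% of the span (exact binomial p = 6.65e-09, one-sided). F2 was the best match of the 6 libraries, a choice for which the p-value makes no allowance. All 7 were F1 sites too, 5 of them among the 79 F1 sites with at least 20 reads, and 3 were on such sites in F3, 3 on the Ahringer clone, 1 in fed animals and 1 in F4. A candidate explanation is that F2 reads were assigned to this library: 3 of the 7 reads (42.9%, Clopper-Pearson interval 9.90 to 81.6) had the same oma-1 and tail sequence as an F2 read, against 6.77% (5.20 to 8.65) of Ahringer reads and 41.8% of F2 reads matched by another F2 read. It stays open. The same share was 9.02% for F1 and 7.28% for F4, below the interval of the 7 reads, but 27.1% for fed animals and 18.1% for F3, within it. A swap of the 2 mutant libraries was not tested, and neither was a biological source of tails in the mutant.

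Signal outside the main measurement appeared in F1, where 24 reads kept intron 2 or ended inside it. Wild-type animals on empty vector had no oma-1 pUG reads at all and give no comparison. Of the F1 reads across the junction, 13 were unspliced and 1407 spliced, 0.915% unspliced (0.488 to 1.56). Another 11 had their tail inside the intron, 5 each at coordinates 8889630 and 8889643 and 1 at 8889621. Fed animals had 1 unspliced read (0.315%, 0.00799 to 1.74) and the authors' table put 1 F3 read on the last base of the intron, where no listed F3 read was placed here. No unspliced read was found in the 4 other libraries with at least 10 sites, with upper bounds of 0.413% in F2, 2.24% in F3, 3.55% on the Ahringer clone and 20.6% in F4. Apart from F2, all these intervals overlapped that of F1. Within F1, intron 1 had 0 unspliced and 4371 spliced reads, an upper bound of 0.0844%, below the interval of intron 2. Intron 3 of F1 had 1 unspliced and 212 spliced reads (0.469%, 0.0119 to 2.59), and intron 4 had 0 and 2. All intervals of this paragraph cover counting error only, since PCR reads are not independent molecules. How many molecules gave the 24 reads of F1 was not checked.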

How the results depend on the processing

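Alternatives with merged sites, means, identical reads or removal of the 5 most-read sites for differences in position, merged sites at equal depth, those for the share 5' of the first zinc finger, the pairs of F1 with F3 and F4, and merged sites for junction bases were chosen after seeing the data. Of 275 alternative values, 187 stayed within the 95% interval of the value reported or, for counts, site numbers, folds and shared sites, within 1.5 times it, and 88 lay outside that limit. For differences in position the intervals were so wide that a value of opposite sign could stay within them. From fed animals to F1, -110 nt without the 5 most-read sites lay within the interval of 137 nt (-159 to 191). For these differences, staying within the limit therefore says little. The difference from fed animals to F4 depended on the weight, at -161 nt (-303 to -46.6) with each site counted once and 1 nt by reads, by sites of at least 2 reads and by merged sites weighted by reads. No paired analysis was possible because each condition had 1 library. The planned share of exon 6 and the whole-transcript background were not run. Unless said otherwise, the cause of a change was not tested.

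Identical reads counted once gave 1605 reads in pAS74-fed animals, 5781 in F2, 3248 in F3 and 495 in F4. Perfect UG tails of at least 18 nt left 416 reads in fed animals, 65 on the Ahringer clone, 0 in the mutant on empty vector, 2079 in F1, 1594 in F2, 664 in F3 and 124 in F4, which lowers counts by construction. With all reads in place of equal depth there were 272 sites in exons in F1, 216 in F2 and 117 in F3. A minimum of 5 reads left 36 sites in fed animals, 21 on the Ahringer clone, 138 in F1, 113 in F2, 55 in F3 and 8 in F4, and a minimum of 2 left 53 in fed animals. Merging within 3 nt left 45, 31, 108, 99, 64 and 9 sites in these libraries, and at equal depth 37.0 in fed animals, 31 on the Ahringer clone, 74.96 in F1, 63.3 in F2 and 8.96 in F4. Counted as sites, wild type over mutant on the Ahringer clone was 18-fold against the floor of 3.

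With each site counted once the median moved to 426 nt in fed animals, 385 nt in F1, 332 nt in F2 and 288 nt in F3. Across settings the difference from fed animals to F1 ran from -110 to 140 nt, from F1 to F2 from -68 to 7 nt, from F3 to F4 from -84 to 63 nt, and from fed animals to F4 from -212 to 1 nt, so their sign is open. The values for F1 to F3 ran from -147 to -52 nt, F2 to F3 from -89 to -35 nt and F1 to F4 from -154 to -18 nt, but the interval lay below 0 in only 1 of the 9 settings for F2 to F3, at -89 nt (-201 to -3.98), and in 1 for F1 to F4, at -120 nt (-252 to -7.95), so these signs are open too. The share 5' of the first finger, by reads, was 59.7% in fed animals, 71.0% in F1, 78.2% in F2, 92.3% in F3 and 97.0% in F4, and by identical reads counted once 41.2%, 63.1%, 68.2%, 86.0% and 94.5%. Merged sites gave 33.3% in F1, 37.4% in F2 and 42.2% in F3. These settings, at least 2 reads per site and removal of the most-read site kept the order fed, F1, F2, F3, F4, but at 5 or more reads per site F3 had 63.6% and F4 62.5%.

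G before the tail made up, by reads, 76.8% in fed animals, 83.1% on the Ahringer clone, 65.1% in F1, 64.2% in F2, 51.3% in F3 and 13.8% in F4. At 5 or more reads per site it was 66.7%, 76.2%, 50.7%, 46.9% and 50.9% in the first 5 of these, and at 2 or more 62.3% in fed animals and 42.4% in F1. Merged sites gave 62.2% in fed animals, 71.0% on the Ahringer clone, 55.6% in F1, 59.6% in F2 and 56.3% in F3. Mismatches in the last 3 bases, with identical reads counted once, were 0.539% in F1 and 0.346% in F2.

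Shared sites over chance, at 5 or more reads per site, were 12.3 between the 2 clones, 4.67, 4.56, 5.62 and 16.1 between fed animals and F1 to F4, and 3.99, 5.08 and 12.7 between consecutive generations. At 2 or more reads the value for fed animals and F4 was 9.55. Merged sites gave 4.39, 4.58 and 11.5 for fed animals with F1, F2 and F4, and 4.08, 4.69 and 8.06 for consecutive generations. At equal depth it was 3.64 for fed animals with F2, 3.74 for F1 with F2 and 4.21 for F2 with F3. Settings that keep fewer sites also raise the highest ratio possible.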

Other observations

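The tests on irregular tails, the count of CG junctions, the comparison of F1 with F3, the removal of the 5 most-read sites, the merged sites, the mean and the identical reads in this part were chosen after the data were seen.

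Many of the most-read sites ended in CG. This dinucleotide was the end of the oma-1 portion at 18.1% (10.5 to 28.0) of sites in pAS74-fed animals, 24.1% (13.5 to 37.6) on the Ahringer clone, 12.1% (8.5 to 16.6) in F1, 11.6% (7.63 to 16.6) in F2, 14.5% (8.70 to 22.2) in F3 and 28.6% (8.39 to 58.1) in F4. Random tail starts placed by the same rule gave 6.90%. By reads the share was 54.5% in fed animals, 47.4% on the Ahringer clone, 38.4% in F1, 36.2% in F2, 37.3% in F3 and 11.8% in F4. At such a junction the G can be the last oma-1 base or the first base of a tail that starts with G.

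Tail sites lay nearer the 5' end in later descendant generations, by sites and by the share 5' of the first zinc finger. Lower depth of later generations is argued against for F1 to F3. With every library thinned to 907 reads the difference F3 minus F1 in median site position was -99.2 nt (95% of draws -130 to -68.0), and -94.3 nt (-125 to -59.5) with neighbouring sites merged. For F3 to F4 depth is not argued against. The thinned medians were 274 nt in F3 and 265.5 nt in F4, and with neighbouring sites merged 297 nt and 299 nt. Whether a few over-amplified sites contribute stays open. The read-weighted difference was -144 nt (-191 to 0) with all sites and -82 nt (-205 to 2) without the 5 most-read ones, so the interval reached 0 before any site was removed, and merged sites counted once gave -52 nt (-156 to 51.1). The interval lay below 0 without the most-read site, at -81 nt (-205 to -37.0), with identical reads counted once, at -92 nt (-161 to -22.0), and for the mean, at -97.1 nt (-150 to -39.0). Stronger amplification of short products in later libraries could not be told apart from a change in the RNAs. Over the 80 sites seen in F1 and F3 the ratio of read shares F3 over F1 fell with distance from the 5' end (Spearman rho -0.350 across sites, which are not replicates), and both would give that. Progressive shortening of the tailed RNAs over generations remains a hypothesis that single libraries leave untested.

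The share of irregular tails differed between the sites of a library. Sites at 80% or more held 36.8% of the irregular reads in F1, 30.95% in F2 and 30.2% in F3, and 0% in fed animals and on the Ahringer clone. In F4, 1 such site held 580 of the 607 irregular reads. The 0% on the Ahringer clone depends on the limit of 80%. There the site at 8889259 had 76.8% irregular tails in 194 reads, and 8889663 had 52.9% in 51. The standard deviation of the irregular share between sites was 33.8 percentage points on the Ahringer clone, against 25.3 in F1, 21.7 in F2, 19.4 in F3 and 2.54 in fed animals. An oma-1 sequence that fixes the irregular share of a site is argued against, since shares were not alike in F1 and F2. Over their 38 shared well-read sites the irregular share had a Spearman rho of -0.275 (bootstrap interval -0.554 to 0.0417). Of 4 sites at 80% or more in either library 0 were so in both. A weaker effect of the sequence stays open, because it would not show if few molecules set the share of a site. In 4 of 5 libraries the spread between sites exceeded all 1000 shuffles of tails among reads, by at least 3.70 times the largest, but in pAS74-fed animals it was 0.802 times the largest shuffled spread. This describes the pattern and would hold for any cause tied to sites, so descent of a site's reads from few amplified molecules was neither supported nor excluded. At the site 8889296 of F4, 543 of 580 reads began with the same 10 tail bases UGUUGUGUGU. No biological explanation was tested, and the irregular shares were not adjusted for listed tail length.

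Libraries shared identical oma-1 and tail sequences. Among the 6 libraries with at least 10 sites, the share of a library's reads that matched a read of another ran from 1.38% (0.714 to 2.39), for Ahringer reads in F4, to 27.4% (25.6 to 29.1), for reads of pAS74-fed animals in F3. Listed tails of up to 3 nt made up 35.4% of reads in pAS74-fed animals, 21.9% on the Ahringer clone, 15.4% in F1, 27.7% in F2, 32.0% in F3 and 11.4% in F4.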
